A study of Rattus norvegicus with 20 samples.

How the data were processed

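Polyadenylated RNA from the nucleus accumbens, the ventral part of the striatum, of Long-Evans rats was sequenced in 20 libraries. Per the labels' protocols, the tissue was dissected and frozen, RNA was extracted with Trizol and a column kit, and libraries were made with the NEBNext Ultra kit, which does not mark the strand, so reads from a gene and an overlapping antisense gene cannot be told apart. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.2.0, SAMtools 1.11, StringTie 2.1.2 and DESeq2 1.28.1, with the Rnor_6.0 build. The headers of the per-library transcript files name StringTie 1.3.6 instead of 2.1.2, run in its estimate-only mode on a merged annotation. Which of these versions made the values is not settled by the sources used here.

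The authors deposited 1 transcript file per library, with coverage, FPKM and TPM for each of 81916 transcripts in 36073 loci, and 1 series table of normalized values. Per the file headers, the transcript coverage, FPKM and TPM values come from StringTie, and 40853 of the transcripts carry no reference identifier. The series table, with 14043 lines and 20 library columns, held FPKM values, which the authors deposited with no statement of the unit and which equalled the FPKM of the transcript files within 1% for at least 99.8% of genes in 18 columns. In the columns of female LBN replicate 5 and male LBN replicate 5, only 20.2% and 19.9% of the ratios lay within 1% of the column's median ratio, with correlations across genes of 0.955 and 0.959, and genes are not independent replicates. The table covered loci holding between 0.109% and 0.156% of the TPM of a library and contained 0 lines for Gapdh, Penk, Drd1 or Mbp. The plan, fixed before the data were examined, had named the table as the main data and TPM summed from the transcript files as its replacement if the table lacked most genes, so TPM became the main measurement. The number of table columns that matched no library was 0, and the table was used only for this comparison.

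From the deposited TPM values, TPM was summed over the transcripts of each StringTie locus, which gives 1000000 in each library. A locus entered the tests with a TPM of at least 0.5 in at least 4 libraries, the size of the smallest group, which left 19747 loci: 12946 with 1 gene symbol, 400 that join 2 or more symbols and 6401 with none. Symbols came from the transcript files. A joined locus was not counted as a gene with a symbol, and its value cannot be split between its genes. Values were tested as log2(TPM + 0.1), so fold changes are on that scale and understate the change of genes with low TPM. The numbers of reads were not recovered from the deposited coverage: depending on the library, 43.9% to 49.5% of low values lay near a whole multiple of the best step, against 20.0% for values without any step. Tests on counts were therefore not run. The bases assigned to transcripts, coverage times length, ranged from 12.4 to 17.9 Gb (gigabases) per library with a median of 14.4, and the deepest library had 1.45 times the bases of the shallowest. Mitochondrial loci took 4.28% to 10.3% of TPM.

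Groups came from the sex and treatment in the labels: among males 4 control and 5 LBN libraries, among females 5 and 6, numbered within each group in the order of submission. All 4 groups entered 1 linear fit in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and a trend of the variance on the mean. A locus was called with a Benjamini-Hochberg adjusted p under 0.05. The comparisons were LBN against control in males and in females, the difference between these effects (the interaction), and males against females within controls and within LBN. The LBN effects of the sexes were also correlated across loci and compared with 100 relabellings of treatment within each sex, the real one included. The labels give 1 sample per rat number and do not state how the rats were allocated, so p-values measure the spread between these samples. No pair of libraries had more than 0.005% of loci with identical TPM, and libraries correlated across loci with r between 0.899 and 0.959, so none was treated as a copy of another. The label descriptions hold a number shared by 5 pairs of samples. Its meaning is not stated in the sources used here and it entered only an alternative fit. Each pair lies within a single treatment, and if the number marks related rats, the p-values may be too small.

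A set of 30 gene lists was fixed before the data were examined: neurotransmitter systems, spiny neuron and interneuron markers, channels, vesicle release, stress-hormone and sex-steroid signalling, immediate early genes, matrix, chromatin modifiers, glia, endothelium, choroid plexus and ependyma, blood, cortex and basal forebrain neighbours, oxidative phosphorylation, ribosomal proteins, mitochondrial transcripts and sex-chromosome genes. The 29 lists with at least 4 tested members were tested with limma's camera, which compares a list with all other loci, with a preset correlation of 0.01 between genes and adjustment over the lists within each comparison. Each call was repeated with an estimated correlation and with fry, which asks whether a list's genes move, on balance, one way. Named genes were chosen by a rule fixed beforehand: up to 10 called genes per direction with a symbol and a mean TPM of at least 50 (or all called symbols if fewer passed), the 5 smallest p-values per direction where fewer than 5 passed, up to 4 called and 3 other members of each called list, the sex-chromosome genes, and optional values for the opioid and ionotropic glutamate lists. The plan stated the minimum of 50 for the series table, and it was applied here to TPM. Genes outside the rule are named in the text as chosen after their values were seen. Some genes that the rule takes are not reported here.

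The fit was tested on simulated values with the means and residual spread of the real loci, 200 of them changed. Each locus was drawn independently and with the same spread in all groups. Real loci vary together within a library, so the shares recovered need not hold for them. At a log2 fold of 1 it recovered 65% of the changed loci for LBN in males, 54% in females, 45% for the interaction, 63% for the sexes in controls and 71% in LBN. At a log2 fold of 2 the shares were 86%, 85%, 83%, 85% and 90%. Alternatives covered the pseudocount, filters on low values, scaling, library weights, the description number as a random block, composition covariates, fits on only the compared groups, and leaving out each library. No genome of the build was used here, and coordinates are those of the deposited files on Rnor_6.0, counted from 1.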

Results

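Polyadenylated RNA was measured in the nucleus accumbens, a ventral striatal region that takes part in reward and motivation, of male and female Long-Evans rats. The series concerns early life adversity and how the sexes differ in resilience to phenotypes related to opioid addiction. Its labels divide the rats into control and LBN, an abbreviation that they do not spell out. In the field it is used for rearing with limited bedding and nesting. Among males, 4 rats were controls and 5 were LBN, and among females 5 and 6. Each library held between 12.4 and 17.9 Gb (gigabases) assigned to transcripts, with a median of 14.4 Gb, and 19747 loci were tested. Levels are given as TPM summed over the transcripts of a locus, and fold changes as log2 of TPM plus 0.1, which understates the change of genes with low TPM.

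Y-linked RNA separated the sexes in all libraries but 1. The summed TPM of the Y loci lay between 74.9 and 102 in the 9 libraries labelled male and between 16.1 and 20.1 in 10 of the 11 libraries labelled female. The library labelled female LBN replicate 4 had a Y sum of 106. It held 41.9 TPM of Eif2s3y, a translation initiation factor gene, and 8.73 TPM of Kdm5d, a histone demethylase gene. An X-linked locus on chromosome X from 74324213 to 74341528, which the other 10 female libraries held at 18.5 to 66.8 TPM and the male libraries at 0.0126 to 0.378 TPM, stood at 0.364 TPM in it. The values of that library contradict its label, and it is called the library labelled female LBN replicate 4 throughout. It was kept in the female LBN group, so the means and library counts of that group include it. It also enters the spread that all comparisons share. Calls that end without it are named below. Female LBN replicate 1 held a trace of Y-linked RNA, with 1.01 TPM of Eif2s3y and 0.696 TPM of Kdm5d.

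**Figure D1:**
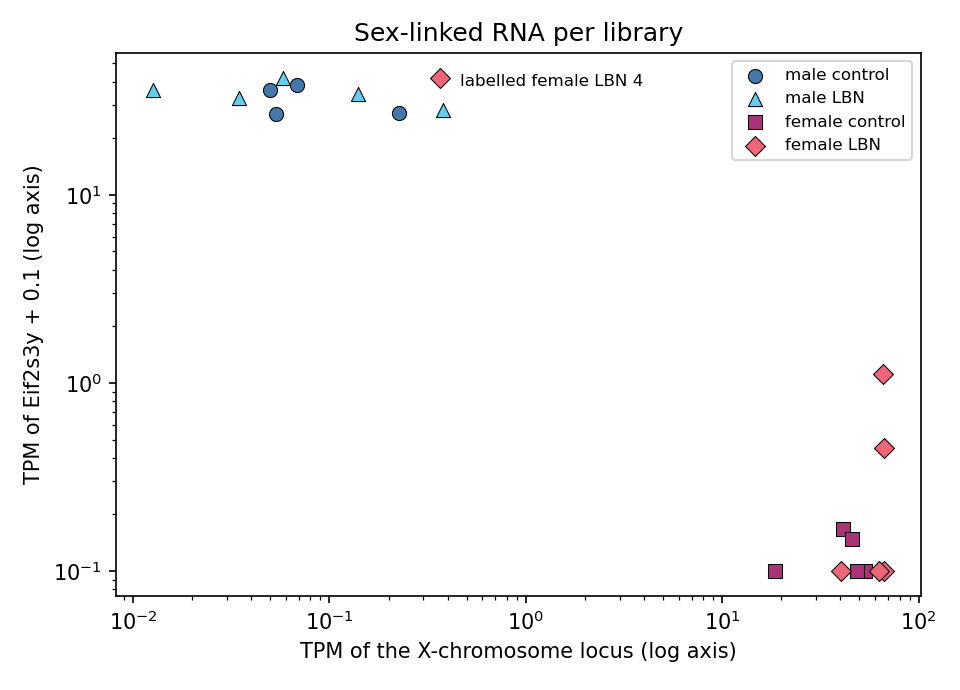
Each point is 1 library of the 4 groups, placed by the TPM of the X-linked locus and the TPM of Eif2s3y plus 0.1, both on log axes. The library labelled female LBN replicate 4, with 41.9 TPM of Eif2s3y and 0.364 TPM of the X locus, lies with the libraries labelled male.

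In males, genes of the choroid plexus and ependyma, the tissues that make cerebrospinal fluid and line the ventricles, were called higher in LBN than in control libraries, and genes of GABA and opioid signalling lower, by a list test with a preset correlation between genes. With an estimated correlation none of the 3 lists was called (adjusted p = 0.28 each), and no single gene passed over all loci. Ttr, which encodes transthyretin, the thyroid hormone carrier secreted by the choroid plexus (chromosome 18, 15532963 to 15540177), had 88 ± 139 TPM (SD, n = 5) in LBN and 2.73 ± 5.3 TPM (SD, n = 4) in control libraries. Single libraries carry these means, which were 26 ± 10.4 TPM (n = 4) without male LBN replicate 4 and 0.0838 ± 0.0984 (n = 3) without male control replicate 3. The log2 level of Ttr was higher in 5 of 5 LBN libraries than the control mean (exact permutation p = 0.0079, two-sided, the smallest this design allows, adjusted p = 0.026 over 10 such tests). Ttr was chosen for this test after its values were seen, so the adjustment does not cover its choice among 19747 loci. Of the 23 tested genes of GABA synthesis, transport and receptors, 21 were lower in LBN, with a median log2 fold change of −0.23. Of the 14 tested opioid receptor and peptide genes, 11 were lower, with a median of −0.26. They included the mu receptor gene Oprm1 (2.09 ± 1.04 TPM, n = 5, against 3.88 ± 0.845, n = 4) and the delta receptor gene Oprd1 (18 ± 4.45 against 24.5 ± 4.22). Of the 26 cytosolic ribosomal protein genes, 24 were higher, with a median of 0.13.

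No single gene passed the test in males. With limma, 0 of 19747 loci had an adjusted p under 0.05, and the smallest adjusted p was 0.409. At the same time 1439 loci had an unadjusted p under 0.05 (958 higher and 481 lower) where uniform p-values give 987. No other tool was run on the loci. Among genes with at least 50 TPM on average, the smallest p-values belonged to genes that did not pass. Fam193b (log2 fold change 0.40), Rps6kb2 (0.50), a kinase gene for ribosomal protein S6, P3h3 (0.62), Leng8 (0.62) and Zfp692 (0.48) had higher values in LBN. Synj1 (−0.55), a phosphatase gene of synaptic vesicle recycling, Nefm (−0.49), a neurofilament gene, Sod2 (−0.24), the mitochondrial superoxide dismutase gene, Fry (−0.34) and Epb41l3 (−0.32) had lower values. Each of these 10 genes lay on that side of the control mean in 5 of 5 LBN libraries. Leaving out male control replicate 3, which had 10.7 TPM of Ttr, gave 1 called locus, Ttr (log2 fold change 7.96, adjusted p = 0.0274 with limma, higher in 5 of 5 LBN libraries). Leaving out male control replicate 2 also gave 1, MSTRG.14761, a locus without a symbol that was named after its values were seen.

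With limma's camera and its preset correlation, 9 of the 29 tested lists were called in males. The choroid plexus and ependyma list was higher (adjusted p = 9.26e-06, median 1.73, 9 of 10 genes and 5 of 5 LBN libraries higher; adjusted p = 0.28 with an estimated correlation). In the 10 tests that hold Ttr, chosen after the data were seen, its list mean differed by 1.97 (exact permutation p = 0.0079, two-sided, adjusted p = 0.026). Over all loci 0 of its genes passed and 5 passed when adjusted over the list alone. These were Ttr (6.45), Ccdc153 (2.07, SE 0.50), Folr1 (3.27, SE 0.95), the folate receptor gene, Clic6 (2.37, SE 0.85) and Tmem212, which was listed at 0 in the controls and had 1.38 ± 1.03 TPM (SD, n = 5) in LBN. Of the same list, Kl differed by −0.12, Aqp1 by 0.07 and Otx2 by 0.03. The GABA list was lower (adjusted p = 0.000452 with camera, median −0.23, list mean lower in 5 of 5 LBN libraries; adjusted p = 0.28 with an estimated correlation). It included Gabrg1, a GABA-A receptor subunit gene (−0.29, SE 0.17), which did not pass alone. The difference of GABA list means went from −0.20 to −0.10 without male LBN replicate 1. The opioid list was lower (adjusted p = 0.0129 with camera, median −0.26, 4 of 5 LBN libraries; adjusted p = 0.28 with an estimated correlation), and this call ended without male LBN replicate 1 (adjusted p = 0.0831 with camera). Within it, Penk, the enkephalin precursor gene, had 1260 ± 583 TPM (n = 5) in LBN and 1360 ± 503 (n = 4) in control libraries. Pdyn, the dynorphin precursor gene, had 267 ± 115 and 319 ± 99.9.

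The striatal interneuron list was also lower in male LBN libraries (adjusted p = 0.0398 with camera, median −0.36, 9 of 13 genes and 5 of 5 libraries; adjusted p = 0.28 with an estimated correlation). Pvalb, the parvalbumin gene, had 40.6 ± 13.2 TPM (n = 5) against 67.7 ± 17.3 (n = 4), and did not pass alone. The potassium channel list was called lower (adjusted p = 0.011 with camera, median −0.11, 16 of 24 genes and 4 of 5 libraries; adjusted p = 0.28 with an estimated correlation). It is named for voltage-gated channels but also holds inward rectifiers such as Kcnj10 (−0.30, SE 0.13). Sodium and calcium channel genes (adjusted p = 0.0315 with camera, median −0.04, 16 of 25 genes and 3 of 5 libraries) and vesicle release genes (adjusted p = 0.0129, median −0.09, 19 of 27 genes and 4 of 5 libraries) were called lower. Both had an adjusted p = 0.508 with an estimated correlation. The sodium and calcium list mean was 5.38 in male LBN replicate 1, while the other male LBN libraries (5.69 to 5.9) lay about where the male controls did (5.69 to 5.84). Oxidative phosphorylation genes were called lower (adjusted p = 0.00771 with camera, median −0.03, 15 of 23 genes and 4 of 5 libraries; adjusted p = 0.549 with an estimated correlation). Sdha, a succinate dehydrogenase gene, differed by −0.17 (SE 0.05). Ribosomal protein genes were called higher (adjusted p = 0.000498 with camera, median 0.13, 4 of 5 libraries; adjusted p = 0.539 with an estimated correlation). Rps2 differed by 0.25 (SE 0.09). The ribosomal list mean was 9.07 in male LBN replicate 1, 8.61 to 8.86 in the other male LBN libraries and 8.61 to 8.85 in male controls. Without male LBN replicate 1, only the GABA and opioid calls were looked at. With fry, 0 of these 9 lists passed. An exact permutation test of the list means per library cannot pass a lone list here, since its smallest p of 0.0079 gives an adjusted p of 0.23 over 29 lists. The choroid plexus list had that value, and the other 8 had 0.69 to 0.921. After quantile normalization 4 were called with camera, and the opioid (adjusted p = 0.0739), potassium (0.0739), vesicle release (0.0739), interneuron (0.13) and sodium and calcium channel (0.167) calls ended. The interneuron call also ended after median-of-ratios rescaling (0.0852) and with a cortical covariate (0.0722).

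**Figure D2:**
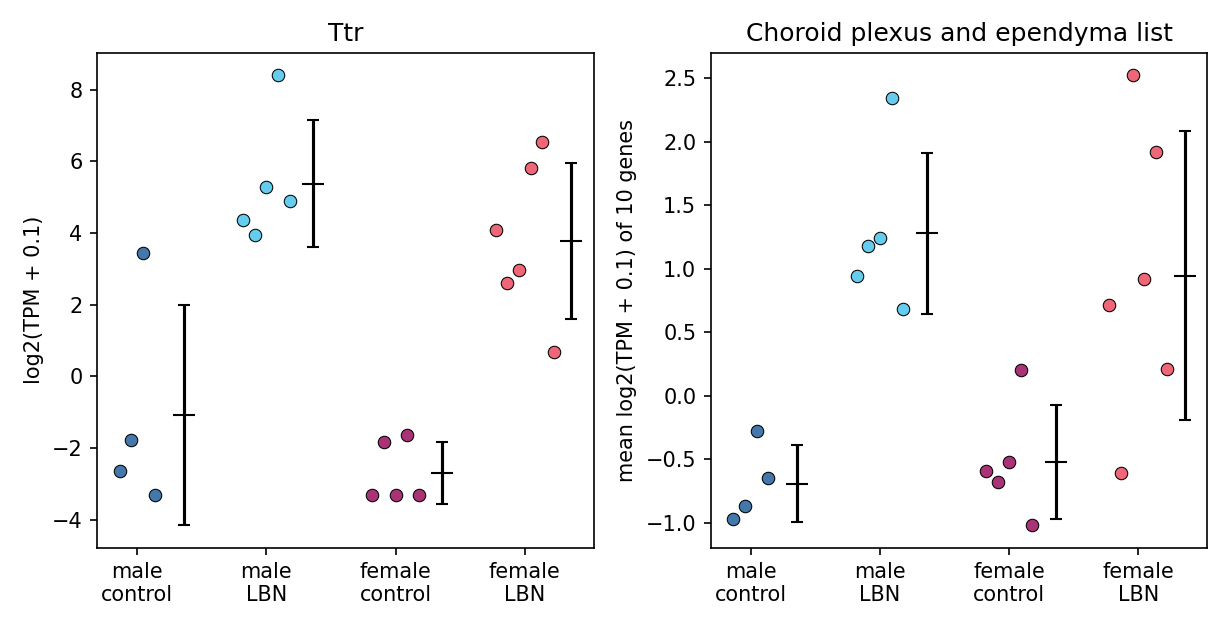
Each point is 1 library, with log2(TPM + 0.1) of Ttr on the left and the mean of that value over the 10 genes of the choroid plexus and ependyma list on the right, by group, and bars beside the points give mean ± SD. The 11 LBN libraries had between 1.49 and 336 TPM of Ttr and 8 of the 9 controls at most 0.221, with male control replicate 3 at 10.7.

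In females, choroid plexus and ependyma genes were again called higher in LBN libraries, and genes of GABA, opioid and dopamine signalling and of oligodendrocytes lower, with the preset correlation. None of these calls was given by an estimated correlation (adjusted p = 0.278 to 0.468), no single gene passed, and the dopamine call ended without the library labelled female LBN replicate 4. Ttr had 30.2 ± 36.7 TPM (SD, n = 6) in LBN and 0.08 ± 0.111 TPM (SD, n = 5) in control libraries (exact permutation p = 0.0043, two-sided, adjusted p = 0.026 over 10 such tests, higher in 6 of 6 LBN libraries). As in males, this adjustment does not cover the choice of Ttr after its values were seen. Without female LBN replicate 5 the LBN mean of Ttr was 17.5 ± 22 TPM (n = 5). All 19 oligodendrocyte and myelin genes were lower, with a median log2 fold change of −0.16. So were 18 of 23 GABA genes (median −0.17), 11 of 14 opioid genes (−0.29) and 16 of 20 dopamine signalling genes (−0.40). Of the 22 genes of DNA methylation and histone modification, 20 were higher, with a median of 0.13. The kappa receptor gene Oprk1 had 9.7 ± 4.5 TPM (n = 6) against 15.6 ± 4.67 (n = 5), and Oprm1 2 ± 0.688 against 3.56 ± 1.54.

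With limma, 0 of 19747 loci passed in females, and the smallest adjusted p was 0.122. Before adjustment, 1489 loci had a p under 0.05 (1174 higher and 315 lower). The smallest p-values among genes with at least 50 TPM did not pass. Srrm2 (0.34), a splicing factor gene, Trmt1 (0.30), a tRNA methyltransferase gene, Ppp6r2 (0.21), Leng8 (0.58) and Ube2q1 (0.72) had higher values in 6 of 6 LBN libraries. Nefm (−0.35), Evi5l (−0.47), Slc6a8 (−0.37), the creatine transporter gene, and Atp5f1a (−0.13), an ATP synthase gene, had lower values in 6 of 6, and Tspyl4 (−1.03) in 5 of 6. Without male control replicate 3, which enters the shared estimate of spread, Ttr was called in females as well (log2 fold change 6.47, adjusted p = 0.0355 with limma, higher in 6 of 6 LBN libraries).

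With camera and its preset correlation, 13 lists were called in females. The choroid plexus and ependyma list was higher (adjusted p = 0.00468, median 1.48, 8 of 10 genes and 5 of 6 libraries; adjusted p = 0.468 with an estimated correlation). Its list mean differed by 1.46 (exact permutation p = 0.03, two-sided, adjusted p = 0.075 over the 10 tests that hold Ttr). Adjusted over the list alone, 4 of its genes passed, Ttr (6.47, SE 1.16), Ccdc153 (4.08 ± 4.22 TPM, n = 6, against 1.36 ± 0.864, n = 5), Dynlrb2 (1.77, SE 0.63) and Clic6 (2.04, SE 0.77), and over all loci 0 did. Without female LBN replicate 3 the LBN mean of Ccdc153 was 2.38 ± 0.807 TPM (n = 5), and that of Dynlrb2 was 1.8 ± 0.862 (n = 5) where all 6 gave 4.39 ± 6.39 and controls 0.864 ± 0.639 (n = 5). The 2 members of the list that were lower were Kl (0.618 to 2.37 TPM in LBN, 1.75 to 2.82 in controls) and Aqp1 (0.234 to 3.17 and 0.755 to 1.88). The oligodendrocyte list was lower (adjusted p = 0.000553 with camera, 5 of 6 libraries; adjusted p = 0.468 with an estimated correlation). Myrf, a transcription factor gene of myelination, differed by −0.31 (SE 0.14). Oligodendrocyte precursor genes (adjusted p = 0.0217 with camera, median −0.16, 8 of 10 genes and 5 of 6 libraries; 0.468 as the adjusted p with an estimated correlation) and microglia genes (adjusted p = 0.0197, median −0.07, 12 of 14 genes and 5 of 6 libraries; adjusted p = 0.472 with an estimated correlation) were called lower. The GABA list was lower (adjusted p = 0.000553 with camera, 4 of 6 libraries; adjusted p = 0.278 with an estimated correlation), and the chloride cotransporter gene Slc12a2 differed by −0.38 (SE 0.16). The opioid list was lower as well (adjusted p = 0.00727 with camera, 5 of 6 libraries; adjusted p = 0.278 with an estimated correlation). Pdyn differed by −0.63 (SE 0.46) and Penk by −0.38 (SE 0.50). The difference of GABA list means went from −0.14 to −0.09 without the library labelled female LBN replicate 4.

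The dopamine list was lower in female LBN libraries (adjusted p = 0.00727 with camera, 4 of 6 libraries; adjusted p = 0.468 with an estimated correlation). The D3 receptor gene Drd3 had 3.13 ± 1.4 TPM (n = 6) against 5.14 ± 1.66 (n = 5). Markers of direct-pathway spiny neurons (7 of 9 genes lower, median −0.16; adjusted p = 0.468 with an estimated correlation) and of indirect-pathway spiny neurons (7 of 9, median −0.29; adjusted p = 0.472 with an estimated correlation), the projection neurons of the striatum, each had an adjusted p = 0.049 with camera and list means lower in 4 of 6 libraries. Both calls ended after quantile normalization (adjusted p = 0.145 each) and median-of-ratios rescaling (0.124 and 0.148). Without the library labelled female LBN replicate 4, the calls of dopamine (adjusted p = 0.213 with camera), direct-pathway (0.328), indirect-pathway (0.459) and precursor genes (0.0586) ended. Interneuron genes were lower (adjusted p = 0.00482 with camera, median −0.26, 11 of 13 genes and 6 of 6 libraries; adjusted p = 0.0692 with an estimated correlation). The neuropeptide Y gene Npy had 233 ± 42.1 TPM (n = 6) against 290 ± 21.1 (n = 5). Potassium channel genes (adjusted p = 0.0447 with camera, median −0.06, 14 of 24 genes and 3 of 6 libraries; adjusted p = 0.468 with an estimated correlation) and oxidative phosphorylation genes (adjusted p = 0.00632, median −0.03, 18 of 23 genes and 3 of 6 libraries; adjusted p = 0.472 with an estimated correlation) were called lower. After quantile normalization both calls ended (adjusted p = 0.151 and 0.0894), and the potassium call also ended after median-of-ratios rescaling (0.117) and with a cortical covariate (0.0961). Genes of DNA methylation and histone modification were called higher (adjusted p = 0.0217 with camera, 6 of 6 libraries; adjusted p = 0.196 with an estimated correlation), such as the histone methyltransferase gene Kmt2a (0.32, SE 0.16). This was the 1 list of the 13 that also passed fry (adjusted p = 0.0128, median 0.13, 6 of 6 libraries), and after median-of-ratios rescaling its camera call ended (adjusted p = 0.0756, median 0.08). An exact permutation test of the list means cannot pass a lone list here either, with a smallest p of 0.0022 and an adjusted p of 0.0628 over 29 lists. The DNA methylation and histone list had that value, and the other 12 had 0.439 to 0.887.

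Of the lists called in neither sex, the ionotropic glutamate receptor list had an adjusted p = 0.0853 in males and 0.343 in females with camera (medians −0.05 and −0.01, 16 and 15 of 28 genes lower). The corresponding adjusted p-values were 0.0697 and 0.246 for metabotropic glutamate receptors and glutamate handling, 0.179 and 0.294 for postsynaptic scaffolds and kinases, 0.0573 and 0.119 for stress-hormone signalling, and 0.733 and 0.384 for matrix and perineuronal nets. Their medians lay between −0.11 and −0.01. Sex steroid genes gave 0.537 and 0.231, cortical excitatory neuron markers 0.993 and 0.417, neighbouring septal and pallidal markers 0.288 and 0.343, and sex-chromosome genes 0.756 and 0.752. Astrocyte genes gave 0.733 and 0.246, endothelial genes 0.733 and 0.865, blood genes 0.993 and 0.0595, and immediate early genes 0.753 and 0.384. Mitochondrially encoded transcripts, with 2 tested members, were too few for the test.

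**Figure D3:**
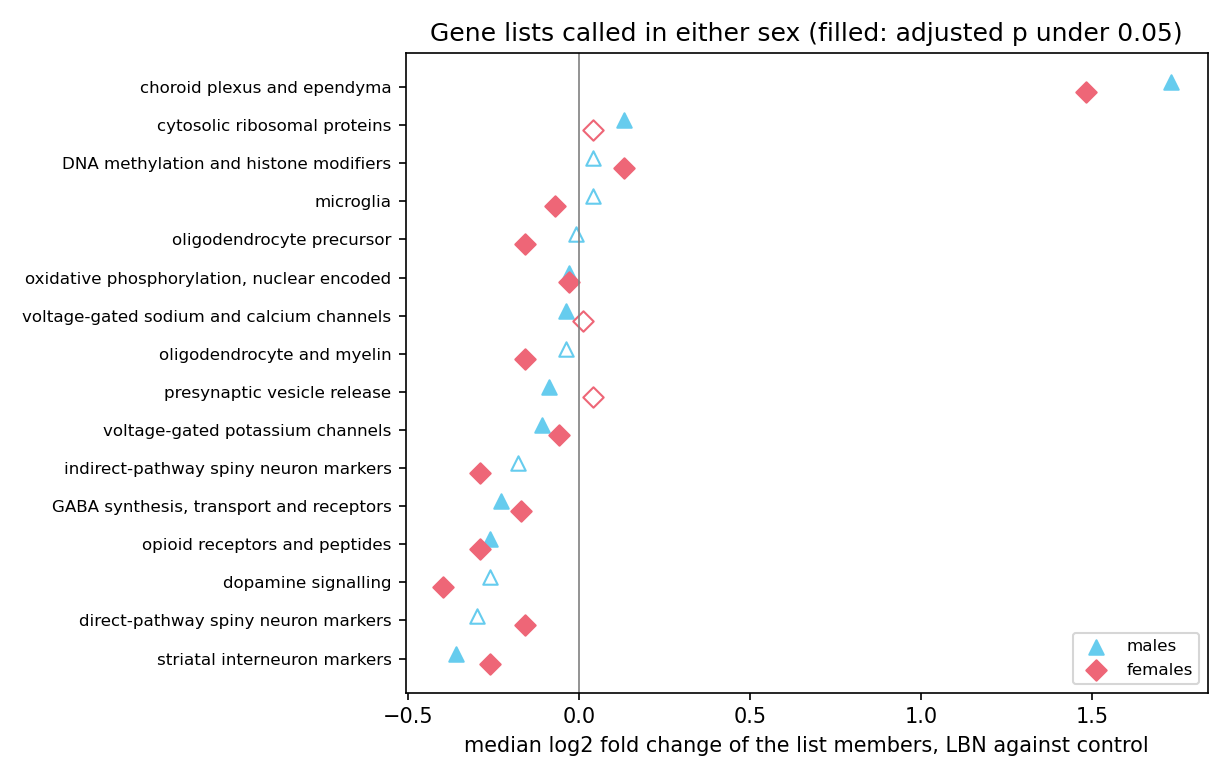
Median log2 fold change of LBN over control in males and females, for the gene lists called in at least 1 sex. Points are filled where the adjusted p of camera with its preset correlation was under 0.05. The choroid plexus and ependyma list lies highest, at 1.73 in males and 1.48 in females, and 6 lists were called in both sexes.

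The sexes were then compared in their response to LBN. The same 6 lists, GABA, opioid, interneuron, potassium channel, choroid plexus and oxidative phosphorylation, were called in both sexes and in the same direction with camera's preset correlation. With an estimated correlation none of them was called in either sex (adjusted p = 0.0692 to 0.549). A gene named for a list in 1 sex need not move alike in the other. Pvalb had 19.3 to 109 TPM in female LBN and 38.4 to 73.4 in female control libraries. Npy had 165 to 345 TPM in male LBN and 204 to 339 in male control libraries. Leng8 (0.62 in males and 0.58 in females), Fam193b (0.40 and 0.29), Rps6kb2 (0.50 and 0.38) and Nefm (−0.49 and −0.35) had an unadjusted p under 0.05 in each sex. Across loci, which are not independent replicates, the LBN effects correlated with a Pearson r of 0.234 and a Spearman rho of 0.364. The same sign was seen in 64.8% of loci. Of 100 relabellings of treatment within each sex, the real one included, 5 gave a Pearson r and 4 a Spearman rho as high. The Pearson r was 0.002 without the male sample of each number shared by a male and a female in the label descriptions, a fit that keeps 1 male control. It was 0.082 among loci with at least 100 TPM in 4 libraries and 0.545 with the choroid plexus list mean as a covariate. That covariate was higher in LBN in both sexes, and a single slope per locus adjusted both effects. The adjusted effects therefore share error, which can raise r, so the 0.545 does not show that the sexes were more alike.

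A difference between the sexes in the LBN effect was called for 1 gene list and no gene. Ribosomal protein genes had a more positive LBN effect in males than in females in 23 of 26 genes (adjusted p = 0.0122 with camera, median 0.09; adjusted p = 0.944 with an estimated correlation and 0.0707 after quantile normalization), such as Rps2 (0.26, SE 0.13). With limma, 0 loci passed for the interaction, with a smallest adjusted p of 0.549. There were 425 loci at an unadjusted p under 0.05, fewer than the 987 of uniform p-values. Over all loci the smallest p-value was that of Nexmif (−1.49). Among genes with at least 50 TPM on average, the smallest p-values, none passing, were those of Tmem64 (0.82), Pak6 (0.57), Mlc1, Osbp2 (0.47) and H1fx (0.29) in the positive direction. In the negative direction they were Araf (−0.43), Synj1 (−0.41), Brsk2 (−0.52), Ctnna2 (−0.26) and Ddit4 (−0.92), a stress-response gene. No difference between the sexes was called for the opioid list (adjusted p = 0.929 with camera, median 0.04, 8 of 14 genes more positive in males) or the choroid plexus list (adjusted p = 0.194, median 0.42, 6 of 10 genes). Simulated values, drawn independently for each locus, gave 45% recovery of a log2 difference of 1 for this comparison. Real loci vary together, so this share need not hold for them.

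Males and females of the control group differed at 9 loci with limma, all on the sex chromosomes. The spread came from all 4 groups, with the library labelled female LBN replicate 4 among them, and the smallest adjusted p was 0.00593. It was 5.21e-13 without that library and female LBN replicate 1, and 5.86e-10 without that library and replicate 3. The 6 on chromosome Y were higher in males in 4 of 4 libraries. Among them were Eif2s3y (32.1 ± 6.05 TPM, n = 4, against 0.023 ± 0.0322, n = 5; log2 fold change 8.05, adjusted p = 0.00731), Kdm5d (8.71 ± 0.966 against 0.00151 ± 0.00337; 6.43, adjusted p = 0.0072) and a Y-linked locus that the files name Ddx3 (7.41, adjusted p = 0.00593). The 3 on chromosome X were higher in females. They were the locus from 74324213 to 74341528 (log2 fold change −7.69) and the overlapping LOC680227 on the other strand (−3.78), which reads without strand cannot separate, and Eif2s3 (37.5 ± 5.8 against 66.4 ± 3.08 TPM; −0.83, SE 0.11, adjusted p = 0.00593, lower in 4 of 4 male libraries). The X-linked genes Ddx3x (−0.48), Kdm6a (−0.49) and Kdm5c (−0.12) did not pass over all loci. Of the fixed list, 5 of the 6 sex-chromosome genes passed when adjusted over the list alone. The smallest p-values among other genes with at least 50 TPM on average, none passing, were those of Tmem64 (−0.68), Ube2n (−0.32), Actr10 (−0.23) and Rheb (−0.26). With camera, 0 of the 29 lists were called, as with an estimated correlation and with fry, and the smallest adjusted p was 0.0866.

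Among LBN libraries, blood, microglia and oligodendrocyte genes were called higher in males than in females, and immediate early genes, which neurons switch on with activity, lower, with the preset correlation and not with an estimated one. The 4 blood genes had a median log2 difference of 0.61 (adjusted p = 0.000152 with camera, 5 of 5 male libraries; adjusted p = 0.21 with an estimated correlation). The beta-globin gene Hbb-b1 had 62.2 ± 13.2 TPM (n = 5) against 38.3 ± 11.9 (n = 6). Of the 4, 3 passed when adjusted over the list alone and 0 over all loci. Oligodendrocyte genes were higher in 16 of 19 cases (adjusted p = 2.92e-05 with camera, median 0.21, 3 of 5 male libraries; adjusted p = 0.756 with an estimated correlation). The myelin basic protein gene Mbp had 4310 ± 776 against 3450 ± 667 TPM. Microglia genes were higher in 12 of 14 cases (adjusted p = 0.000152 with camera, median 0.16, 4 of 5 libraries; adjusted p = 0.541 with an estimated correlation). Tyrobp differed by 0.34 (SE 0.11). Immediate early genes were lower in 18 of 21 cases (adjusted p = 0.0208 with camera, median −0.41, 4 of 5 libraries; adjusted p = 0.756 with an estimated correlation). Npas4 had 7.32 ± 1.55 against 22.6 ± 17.8 TPM and Fosb 15 ± 4.05 against 26.8 ± 11.9. In controls the blood (median 0.28, adjusted p = 0.0866 with camera), oligodendrocyte (0.07, 0.0866), microglia (0.05, 0.425) and immediate early lists (−0.19, 0.417) had the same directions without a call. For the interaction, their adjusted p-values with camera were 0.263, 0.168, 0.0848 and 0.535. These lists were therefore not shown to differ between the sexes only with LBN.

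The other lists called between LBN males and females included oligodendrocyte precursor genes (adjusted p = 0.0017 with camera, median 0.25, 9 of 10 genes and 4 of 5 male libraries higher; adjusted p = 0.541 with an estimated correlation). Astrocyte genes (adjusted p = 0.0427 with camera, median 0.11, 12 of 15 genes and 3 of 5 libraries), endothelial genes (0.0376, median 0.09, 9 of 12 and 4 of 5) and ribosomal protein genes (0.031, median 0.03, 17 of 26 and 4 of 5) each had an adjusted p = 0.756 with an estimated correlation. The astrocyte call ended without the library labelled female LBN replicate 4 (adjusted p = 0.0566 with camera) and after quantile normalization (0.147), as did the ribosomal call after the latter (0.341), and the endothelial call ended with a cortical covariate (0.0539). With limma, 12 loci differed, 6 in each direction, and 10 lay on X or Y, including all 9 called in controls. The others were Nexmif on X (2.83 ± 0.673 TPM, n = 5, against 6.7 ± 1.69, n = 6; −1.22, SE 0.18, adjusted p = 0.0177, lower in 5 of 5 male libraries), Rasgef1b on chromosome 14 (17.1 ± 1.36 against 23.2 ± 1.32; −0.44, SE 0.08, adjusted p = 0.0387, lower in 5 of 5) and MSTRG.8893 on chromosome 17, without a symbol (−0.69). In controls Nexmif was not higher in females, with 2.77 to 3.58 TPM against 3.35 to 4.4 in males. The library labelled female LBN replicate 4 had 5.06 TPM of it, above the LBN males (1.71 to 3.31). Without the library labelled female LBN replicate 4 the calls of Rasgef1b (−0.44, adjusted p = 0.0921 with limma) and MSTRG.8893 ended, and that of Rasgef1b also ended after quantile normalization (0.112) and median-of-ratios rescaling (0.121). With the library labelled female LBN replicate 4 in the female group, Eif2s3y differed by 6.03 (adjusted p = 0.044 with limma, higher in 5 of 5 male libraries), and without it Eif2s3y differed by 7.30 (adjusted p = 1.75e-07). The count was 0 without female LBN replicate 1, 5 or 6 or male LBN replicate 1. It was 3 without female LBN replicate 3 or male LBN replicate 2, 3 or 5, 4 without female LBN replicate 2, 7 without male LBN replicate 4, and 10 without the library labelled female LBN replicate 4.

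Libraries of all groups also varied in their content of cortical and striatal neuron markers. Slc17a7, a vesicular glutamate transporter gene of cortical neurons that was chosen after its values were seen, ranged from 17.1 TPM in female LBN replicate 3 to 2200 TPM in the library labelled female LBN replicate 4, and Penk was lowest in that library and reached 2030 TPM. Over the deviations of the 20 libraries from their group means, the mean of the cortical marker list correlated with that of spiny neuron markers with a Pearson r of −0.70 (permutation p = 0.0016, adjusted p = 0.008 over 5 relations; Spearman rho −0.86, permutation p = 1e-05, the smallest the permutations can give, adjusted 5e-05) and of −0.69 without the 2 libraries farthest from the median. It correlated with the GABA list mean with an r of −0.57 (permutation p = 0.012, adjusted 0.02; rho −0.61, p = 0.0052, adjusted 0.0087; −0.49 without those 2) and with the opioid list mean with an r of −0.57 (permutation p = 0.0091, adjusted 0.02; rho −0.62, p = 0.0041, adjusted 0.0087; −0.58 without those 2). The cortical list mean differed between LBN and control libraries by 0.17 in males (exact permutation p = 0.77, two-sided) and by −0.05 in females (exact permutation p = 0.98, two-sided), on the log2 scale.

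**Figure D4:**
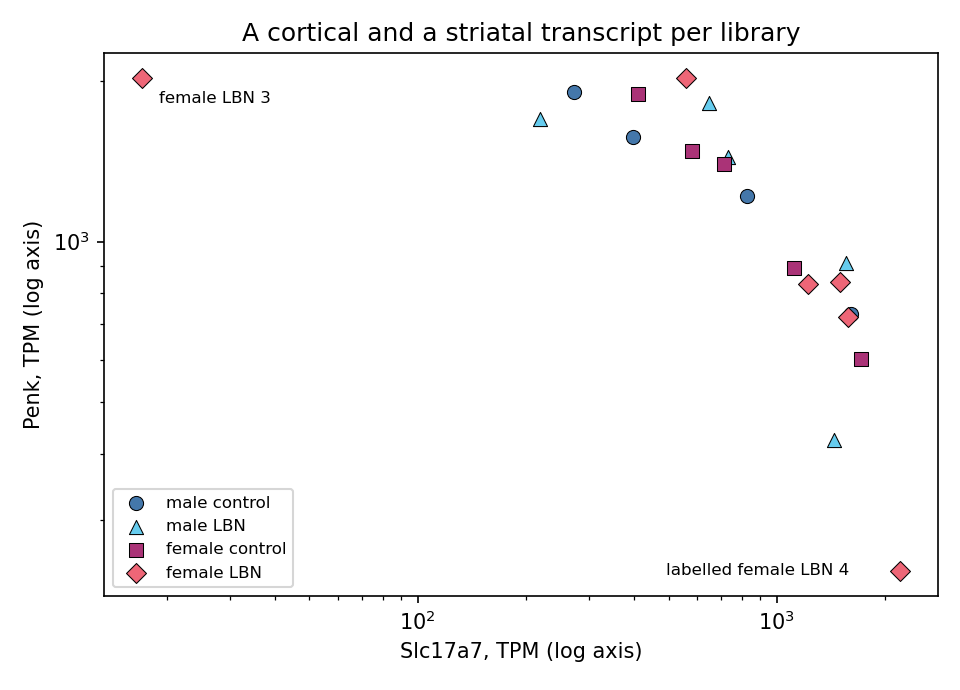
Each point is 1 library of the 4 groups, placed by its TPM of Slc17a7, from cortical neurons, and of Penk, from striatal neurons, both on log axes. The libraries run from 17.1 TPM of Slc17a7 in female LBN replicate 3, which had 2030 TPM of Penk, to 2200 TPM in the library labelled female LBN replicate 4, which had the lowest Penk.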

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

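The tests of Ttr and of Y-linked RNA were chosen after these results were seen, and 2 of the Ttr tests were settled after their values were known: a permutation p of 0.05 or above at first counted against choroid plexus tissue, and depth was at first tested by the correlation of Ttr with assigned bases (r = 0.15, permutation p = 0.52, adjusted 0.52, rho −0.03, n = 20). The tests of the GABA and opioid lists and of other splits of the samples were fixed before their results. A library was singled out where its gap to the nearest library of its group was large against the group's range, which happened 13 times in 148 tests of 37 measures, where chance gives about 7.

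Ttr and other choroid plexus and ependyma genes were higher in LBN libraries of both sexes, and Ttr stood apart in 2 libraries, at 336 TPM in male LBN replicate 4 (others 15.3 to 38.9) and 10.7 TPM in male control replicate 3 (others at most 0.192). LBN samples with rat numbers above all controls are argued against as the whole cause. The test took the 6 LBN samples not numbered above all controls and pooled the sexes. Their log2 Ttr was higher than that of the controls (exact permutation p = 6e-04, two-sided). Among them, female LBN replicate 5 (93.4 TPM) is numbered below all controls. Whether the numbers follow time is not stated in the sources used here, so the test speaks of the numbers alone. Depth is argued against as well, since mean assigned bases in male LBN libraries were 0.982 times those of male controls (1.05 times in females). Tissue of the choroid plexus or ventricle wall carried along in dissection stays open, and its test decided nothing: within groups, Ttr and the mean of the other list members had an r of 0.27 (permutation p = 0.25, adjusted 0.31, rho 0.22, permutation p = 0.36, n = 20, 0.23 without the 2 farthest libraries). That mean mixes choroid plexus with ependyma genes. Male LBN replicate 4 also had the highest Folr1 (4.47 TPM) and Clic6 (3.23) of the male libraries. Female LBN replicate 3 had more of both (11.4 and 3.36) with only 7.66 TPM of Ttr. An effect of LBN on these genes stays open and cannot be told apart from a difference in dissection, because the sources used here do not give the order of dissection.

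GABA and opioid lists were lower in LBN libraries of both sexes with camera's preset correlation, a call that an estimated correlation did not give. With the cortical marker mean as a covariate, the GABA list kept an adjusted p of at most 0.000111 in both sexes with camera (medians without it −0.23 and −0.17, lower in 5 of 5 and 4 of 6 libraries). The opioid list kept one of 0.0134 and 0.00754. By the planned rule this counts against more cortical tissue in LBN dissections as the whole cause. The rule does not decide it, since camera's preset correlation was 0.01 and the estimated one of the GABA list 0.123. The cortical list mean also differed by only 0.17 in males and −0.05 in females, so the covariate could remove little. By the planned rule, which has the same limit, a single low library per sex is counted against as the whole cause for the GABA list (highest adjusted p = 0.0273 with camera without male LBN replicate 1, and 0.00341 without the library labelled female LBN replicate 4). The difference of list means went from −0.20 to −0.10 and from −0.14 to −0.09 without them, and the opioid list lost its call in males (0.0831 with camera). Since the same lists gave adjusted p-values of 0.28 and 0.278 with an estimated correlation, chance variation shared by the genes of a list stays open, as does an effect of LBN.

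Y-linked RNA summed to 106 TPM in the library labelled female LBN replicate 4 (other female LBN libraries 16.1 to 19.3), above the 74.9 to 102 of the male libraries. A mixture of male and female RNA is argued against by the X-linked locus at 0.364 TPM, inside the male range. The X-linked genes Kdm6a (4.98 TPM, males 4.78 to 7.4) and Ddx3x (64.6, males 44.9 to 67.8) also lay inside the male ranges. Eif2s3, at 48.9 TPM, lay between the males (32.6 to 44.5) and the other females (56.1 to 70.9). A swap with a library labelled male in this series is argued against by the 0 male libraries with female values. A sample from a male animal under a female label may account for the values, at a Y sum of 106. Where such a sample came from is open, and the same library also had 17.9 Gb of assigned bases (others 12.9 to 14.7) and a dopamine list mean of 5.00 (others 6.09 to 6.70), on the log2 scale of all list means here.

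Other libraries that stood apart are given as values. Male control replicate 4 had a dopamine list mean of 6.04 (others 6.59 to 6.64) and a direct-pathway marker mean of 4.74 (others 5.50 to 5.60). Male LBN replicate 1 had an indirect-pathway marker mean of 4.77 (others 5.74 to 6.07), and male LBN replicate 5 an oxidative phosphorylation mean of 8.31 (others 8.48 to 8.54). Female LBN replicate 3 had a cortical marker mean of 2.81 (others 5.53 to 6.58) and a metabotropic glutamate list mean of 4.68 (others 5.06 to 5.29). Female control replicate 2 had a stress-hormone list mean of 4.41 (others 3.91 to 4.02), and male control replicate 3 had 0.226 TPM of the X-linked locus (others 0.0498 to 0.0687). The LBN effect on ribosomal protein genes differed between the sexes (interaction, adjusted p = 0.0122 with camera, median 0.09, 23 of 26 genes more positive in males; adjusted p = 0.944 with an estimated correlation).

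Other splits of the same samples bear on each count. For LBN against control, a count of 0 called loci is reached by all 100 splits in males (highest other 3), in females (highest other 512) and for the interaction (highest other 50) whatever the samples, so it decides nothing. Chance is not excluded for the loci at an unadjusted p under 0.05: 23 of 100 splits gave at least the 1439 of males (highest other 3438), 12 the 1489 of females (highest other 4374) and 96 the 425 of the interaction (highest other 2759). The 512 loci called by another split in females and the 50 for the interaction point to a structure of the samples. Whether the varying content of cortical and striatal markers accounts for these calls was not tested. For the sexes in controls, chance is argued against, since 1 of 100 splits, the real one, gave 9 loci (highest other 2). In LBN, 2 of 100 gave at least 12, which is under the limit of 5, but another split gave 47. Chance is therefore not excluded for the LBN count, and the 47 loci again point to a structure of the samples. For 9 of the 12 loci, those on X or Y that were also called in control rats, chance is argued against. Without the library labelled female LBN replicate 4, their adjusted p was 1.96e-10 to 0.000985 with limma. For the correlation of male and female effects, 5 of 100 relabellings gave a Pearson r as high as 0.234 (highest other 0.397), which does not exclude chance, and 4 of 100 a Spearman rho as high as 0.364 (highest other 0.506), which is just under the limit of 5, so the 2 measures divide.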

How the results depend on the processing

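Covariates for cortical, choroid plexus and first-residual-component content, other filters at 5 TPM, pseudocount 1, quantile-normalized, covariate and permuted list tests, and fits without chosen libraries were chosen after seeing the data. Tests on counts (edgeR and DESeq2) were not run, since whole reads were not recovered, and the cause of a change below was not tested unless named. In males, 0 called loci became 1 without male control replicate 2 or 3, a range of 0 to 1. In females, 0 became 2 with a pseudocount of 10, 5 with array weights and 1 in a fit of the 2 compared groups only. The 9 loci between control males and females ranged from 7 to 10 with each library left out and were 6 with a pseudocount of 10 or a filter at 5 TPM, and the 12 between LBN males and females were 7 without a filter, 7 at 5 TPM, 5 with an oligodendrocyte covariate, 6 with a choroid plexus covariate, 0 in a fit of the 2 groups and 0 to 10 with each library left out (0 without female LBN replicate 1, 5 or 6 or male LBN replicate 1). At 100 TPM in 4 libraries both counts were 0, where the Y loci lie below the filter. The interaction stayed at 0 in every fit run. The correlation of 0.234 was 0.082 at 100 TPM, 0.545 with a choroid plexus covariate (whose slope both effects share, which can raise r) and 0.002 without the male sample of each shared number, where the lone male control is assumed to vary like the other groups. It was 0.182 to 0.27 with each library left out. The 31 list calls became 0 with an estimated correlation, 1 with fry, 19 after quantile normalization and 26 after median-of-ratios rescaling. Exact permutation of list means, not run for the interaction, gave 0 calls, but it cannot pass a lone list (smallest adjusted p 0.23 in males and 0.0628 in females and between the LBN sexes), so its 0 says nothing of a list at that value. Males' 9 became 0, 0, 4 and 8 in that order (0 with permutation), females' 13 became 0 with an estimated correlation, 1 with fry, 9 after quantile normalization, 9 after median-of-ratios rescaling and 0 with permutation, the interaction's 1 became 0, 0 and 0 after quantile normalization and 3 with a cortical covariate, and the LBN sexes' 8 became 0 with an estimated correlation, 0 with fry, 6 after quantile normalization and 0 with permutation. Of 163 named gene and comparison pairs, 148 kept their direction and side of the threshold in the scaling, cortical-covariate and leave-one-out fits, and 4 of 10 called pairs did. Direction reversed in 6 pairs, none called. In males Penk was −0.47 to 0.15 with each library left out (above 0 only without male LBN replicate 1), Pnoc −0.03 to 0.22, Cpe −0.06 to 0.03 (0.02 after quantile normalization) and Rgs9 −0.50 to 0.08. In females Pnoc was −0.21 to 0.19 and Rgs4 −0.02 to 0.27, while Penk stayed between −0.62 and −0.00. The 5 pairs of samples that share a number had correlations of deviations of 0.08, 0.04, −0.15, −0.09 and 0.11. These values do not settle whether paired samples are related. The −0.15 is that of male LBN replicates 2 and 3, where deviations from a shared group mean pull r below 0. As a random replicate block (consensus correlation 0.19) the number gave 0, 0, 0, 10 and 11 called loci for males, females, interaction, sexes in controls and sexes in LBN. Numbers of reads are unknown, so the depth behind a gene's TPM limits low genes such as Oprm1 to an unknown extent.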

Other observations

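A set of genes, chosen after their values were seen, had an unadjusted p under 0.05 and the same sign in both sexes, with 0 passing limma's adjusted test in either. Of those with higher values in LBN, Srrm2, a splicing factor gene, differed by 0.24 in males and 0.34 in females, Pnn, a gene of the exon junction, by 0.21 and 0.22, and Srsf11, a splicing regulator gene, by 0.16 and 0.17. The neurofilament genes Nefm and Nefl differed by −0.49 and −0.24 in males and by −0.35 and −0.16 in females. Cxcl14, a chemokine gene, differed by −0.34 and −0.35, and Tesc by −0.56 and −0.51. In all, 387 loci had an unadjusted p under 0.05 in both sexes, and 376 of them had the same sign, with 319 higher, where independent sets would share 57, and 57 lower, where they would share 7.7. These genes were not tested for enrichment, and loci within a library vary together, so the counts carry no p-value.

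The largest component of the residual variation between libraries held 17.9% of it. Over the 20 libraries it correlated with the cortical list mean, as deviations from group means, with a Pearson r of 0.92 (permutation p = 1e-05, the smallest the permutations can give, adjusted p = 1e-05 over 2 relations; Spearman rho 0.94, permutation p = 1e-05, adjusted 1e-05; r 0.92 without the 2 farthest libraries). With the mean of spiny neuron markers it correlated with an r of −0.90 (permutation p = 1e-05, adjusted 1e-05; rho −0.96, permutation p = 1e-05, adjusted 1e-05; r −0.92 without the 2 farthest). The list genes are among the loci the component was taken from, and this test was chosen after the values were seen. With this component as a covariate, added after seeing the data, limma called 0 loci in males, 0 in females, 0 for the interaction, 9 between the sexes in controls and 16 in LBN.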
